A study of Homo sapiens with 12 samples.

How the data were processed

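Total RNA was measured on 12 Affymetrix 3′ expression arrays, 1 per sample. The samples were Kasumi-1 cells, an established acute myeloid leukaemia line carrying the RUNX1-RUNX1T1 fusion. Per the labels' protocols, the cells were transduced with a retrovirus, either mock or carrying wild-type RAD21, and GFP-marked cells were sorted 48 h later. Each arm had 3 arrays in each of 2 independent experiments, which gives 4 groups of 3 arrays. Whether the 3 arrays of a group came from separate cultures is not given in the sources used here, so p-values measure only the spread between these arrays, which may be technical.

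The deposited values are probe set intensity on a linear scale, 1 column per array, made by the authors. The method that summarised and scaled them is not given in the sources used here. They ran from 0.58 to 10288.37, with no value at or below 0 and none missing. The median of an array lay between 20.45 and 23.01, and the mean between 219 and 226 in experiment 1 and between 196 and 199 in experiment 2. The table held 54639 probe sets. Of these, 26 were controls, 41091 had exactly 1 gene symbol in the platform annotation, 1801 had several and 11721 had none there. Symbols were updated through gene identifiers with a RefSeq gene table, which held 41043 of the single-gene probe sets and changed the symbol of 43. No genome was used, so no coordinates are given.

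Intensities were log2 transformed with no pseudocount. Each gene was represented by the probe set with the highest mean over all arrays, which left 19752 genes. The spread depended on the level. Over 4 classes of 4938 genes ranked by level, the median SD of log2 values within a group was 0.66 in the dimmest, with a median intensity of 5.24, and 0.048 in the brightest, with a median intensity of 709. The number of arrays and the brightness of a probe set limited the precision.

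RAD21 arrays were compared with mock arrays by limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) with the experiment as a fixed term, and p-values were adjusted by Benjamini-Hochberg over the 19752 genes at 0.05. The change within each experiment and the difference between experiments came from a fit of the 4 group means to all arrays. All tests were two-sided. Folds were taken from log2 differences, and errors are standard errors of the fit unless an SD is named. For 30 gene lists with 742 genes, of which 670 were measured, camera was run with a preset correlation of 0.01 between genes, and its p-values were adjusted over the lists. Camera with an estimated correlation and fry were run beside it.

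The groups, designs, gene lists and most alternatives were fixed before the data were examined. So was the rule for the genes named. It took RAD21 and the measured members of the cohesin list, the 12 largest rises and 12 largest falls among genes past the threshold with the same sign in both experiments, and up to 4 members with the smallest p from each list that passed or had a member past the threshold. Unnamed loci, olfactory receptors, snoRNA and miRNA genes, Y-linked genes and XIST were left out of it. Genes named outside this rule are said to be chosen after their values were seen.

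The alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 40% of genes, testing all probe sets, a variance prior with trend and robust, replicate number as a block, no experiment term, triplicates averaged, a random block of arm within experiment, the arrays of 1 experiment alone, a test against a fold limit of 1.1, and leaving out each array. A pseudocount of 16, the other RAD21 probe set and the alternatives for the share of genes that moved the same way in both experiments were added after the data were seen.

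The steps were tested on simulated data with the means and spreads of the 19752 real genes, in which 200 genes were changed. In the pooled comparison 26.9% of genes changed 1.2-fold, 58.2% of those changed 1.5-fold and 60.6% of those changed 2-fold were called, and 9 of 122 calls were false. The pooled simulation also held the shifted list of 20 genes described below, whose calls count among the 122 but not as false. Within experiment 1 the shares were 3.0%, 40.3% and 47.0%, with 4 false calls of 64. Within experiment 2 they were 7.5%, 40.3% and 47.0%, with 6 of 69. For the difference between experiments they were 0%, 25.4% and 40.9%, with 2 of 46. Among 30 simulated lists of 20 genes, the only one shifted, by 1.2-fold, was called and 0 of the others were. The noise was drawn independently for each gene, and the shifted list was taken only from genes above the median level. Real lists had estimated correlations between genes of up to 0.597 over both experiments, so the simulation does not measure how often real lists are called falsely. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.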

Results

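Gene expression was measured in Kasumi-1 cells, a myeloid leukaemia line, 48 h after retroviral transduction with a mock vector or with wild-type RAD21, a subunit of the cohesin ring that holds sister chromatids together and shapes chromatin loops. The data comprised 12 arrays in 4 groups of 3, with both arms in each of 2 independent experiments. On the log2 scale, arrays of the same arm and experiment correlated at 0.966 to 0.973 over all probe sets, arrays of different arms within an experiment at 0.967 to 0.973, and arrays of different experiments at 0.889 to 0.900. The experiment therefore separated the arrays far more than the arm did, and each comparison below kept the experiment as a term or was made within it.

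RAD21 itself was read by a pair of probe sets. The brighter one gave 2261 ± 42 (SD, n = 3) in mock and 2110 ± 73 in RAD21 arrays of experiment 1, and 1826 ± 52 against 1920 ± 47 in experiment 2. Its change over both experiments was -0.01 ± 0.04 on the log2 scale (adjusted p = 0.939). The dimmer one gave 144 ± 14 in mock and 153 ± 19 in RAD21 arrays of experiment 1. In experiment 2 it gave 261 ± 22 and 362 ± 16, a 1.39-fold higher mean with all 3 RAD21 arrays above all 3 mock arrays. There its limma p was 0.00179 unadjusted and 0.127 adjusted over all probe sets. Its unadjusted limma p in experiment 1 was 0.483. Those of the brighter probe set were 0.0928 in experiment 1, where it was lower, and 0.205 in experiment 2. Whether either probe set lies within the transferred copy is not given in the sources used here, so these values do not check the labels of the arms. In what follows "RAD21 arrays" are the arrays labelled RAD21.

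**Figure D1:**
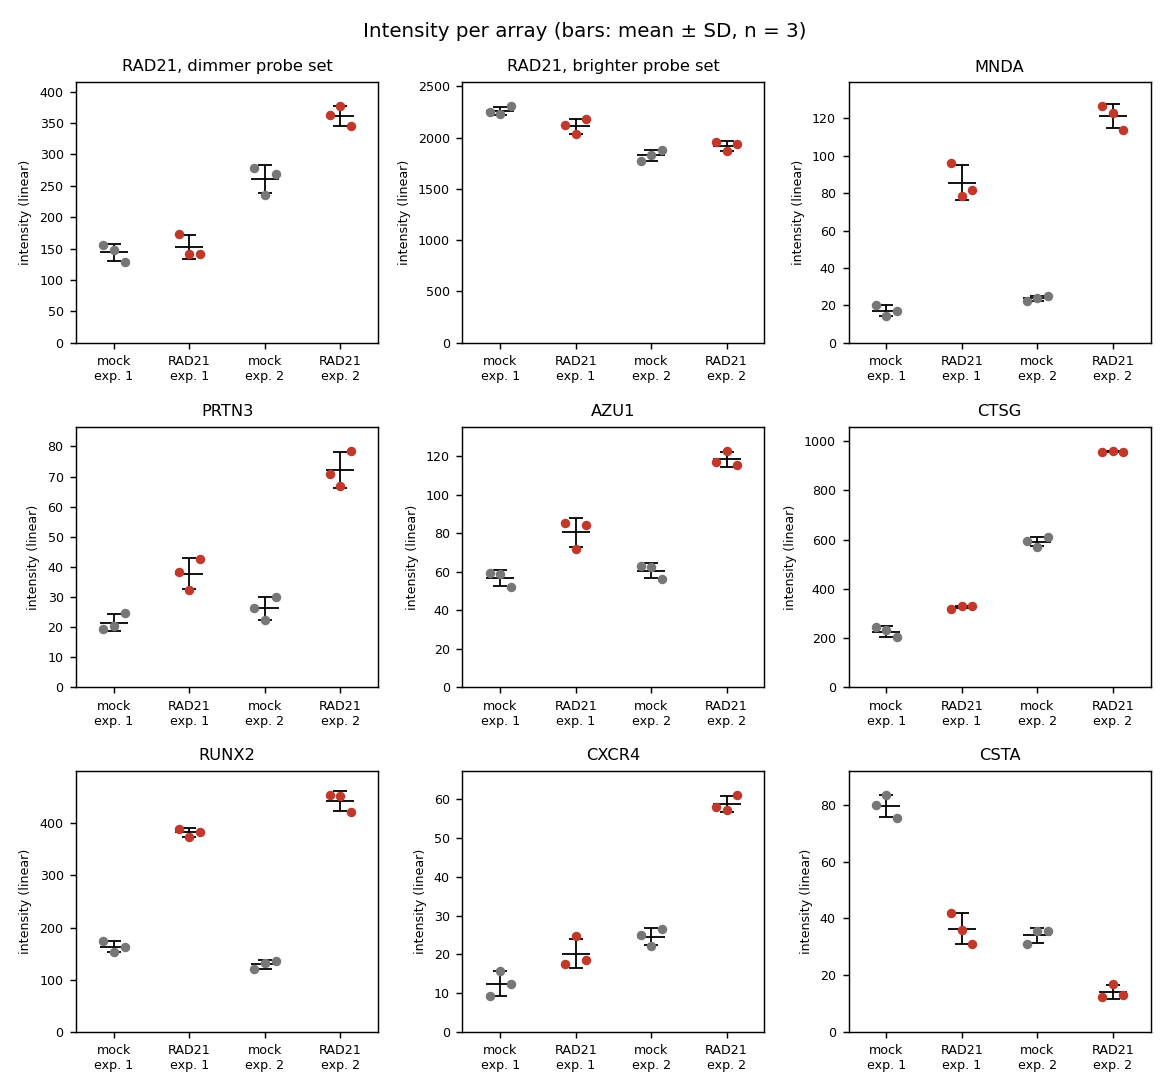
Linear intensity of each array (points) for both RAD21 probe sets, 6 genes that were higher and CSTA, which was lower, in RAD21 arrays, with mock arrays in grey, RAD21 arrays in red, and bars for the mean ± SD of 3 arrays. The brighter RAD21 probe set lies between 1773 and 2307 in all 12 arrays, while MNDA averages 17.2 and 23.7 in mock arrays and 85.6 and 121 in RAD21 arrays.

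The other cohesin genes gave no call over both experiments. None of the 23 measured subunits and regulators passed the threshold, whether adjusted over all genes or adjusted over the list alone. The core subunits SMC1A (-0.01 ± 0.03, log2), SMC3 (-0.06 ± 0.03), STAG1 (0.01 ± 0.03) and STAG2 (-0.01 ± 0.03) and the loader NIPBL (0.00 ± 0.04) had adjusted p-values of 0.537 to 0.999. The acetyltransferase ESCO1 passed in experiment 2 (0.21, adjusted p = 0.0272) but not in experiment 1 (-0.10, adjusted p = 0.352), and its change differed between the experiments (difference 0.31 ± 0.06, adjusted p = 0.0443). Leaving out 1 array ended the call in experiment 2 in 8 of 12 cases (adjusted p up to 0.102) and the call of the difference in 12 of 12 (0.0792 to 0.116). The meiotic subunit SMC1B had the largest value in the list, -1.02 ± 0.28 (adjusted p = 0.147), at group means of 3.2 to 7.0, near the bottom of the intensity range. It was called only without RAD21 replicate 2 of experiment 1 (-1.29, adjusted p = 0.00201), and with a pseudocount of 16 its change was -0.21 (adjusted p = 0.143).

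Over both experiments, the genes with the largest rises in RAD21 arrays were led by MNDA, an interferon-inducible nuclear antigen of myeloid cells, which rose 5.06-fold (log2 2.34 ± 0.09, adjusted p = 2.02e-06, n = 6 arrays per arm), with 5.01-fold in experiment 1 and 5.11-fold in experiment 2. RUNX2, a transcription factor of the family that includes RUNX1, rose 2.83-fold (adjusted p = 7.16e-05) from 163 to 382 in experiment 1 and from 129 to 443 in experiment 2. That rise rests on its brightest probe set. Its other probe sets, at levels of 2.99 to 8.09, were not called, with log2 changes of -0.36, -0.38, -0.49, -0.27 and 0.33. The homeobox gene CUX2 rose 2.98-fold, the actin-binding protein gene ABLIM1 3.51-fold and the receptor tyrosine kinase FGFR1 2.50-fold. The FGFR1 value is uncertain, since it comes from the brightest of 7 probe sets and none of the other 6 was called, with log2 changes of 0.03, -0.01 and 0.30 in the 3 at levels of 130 to 145. The chemokine receptor CXCR4 rose 1.99-fold (adjusted p = 0.0119), with 1.07 and -0.34 on the log2 scale, neither called, in its other probe sets at levels of 8.66 and 22.7. The folds of MNDA, ABLIM1 and CXCR4 are uncertain in size, since their mock means (17.2 and 23.7, 19.8 and 14.9, 12.4 and 24.6) lie near or below the array medians of 20.45 to 23.01, where background is a larger part of the signal. With a pseudocount of 16 their log2 changes were 1.70, 1.21 and 0.62, each called. The largest falls among genes with group means above 10 included the protease inhibitor CSTA, lower by a ratio of 2.32 (-1.21 ± 0.10, adjusted p = 0.000216, and -0.80 with the pseudocount, at a RAD21 mean of 14.1 in experiment 2), the early activation antigen CD69, lower by a ratio of 1.97 (-0.98 ± 0.06, adjusted p = 3.89e-05), and the TNF receptor gene TNFRSF1B, lower by a ratio of 1.76 (-0.82 ± 0.06).

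In all, 237 of 19752 genes passed adjusted p under 0.05, 131 higher and 106 lower in RAD21 arrays (101 and 60 with each array centred on its median), and 2400 had an unadjusted p under 0.05. A change of at least 1.2-fold was met by 166 of them (95 higher, 71 lower), of at least 1.5-fold by 58 and of at least 2-fold by 17. The other named rises were CD24, SDC1, PRTN3, PTPRM, ADGRL3 and AUTS2, at 2.05- to 2.72-fold. CD24 was read by a probe set of the kind that can match several transcripts. Its 5 other probe sets, of the same kind, were all higher, by 0.92 to 1.43 on the log2 scale, with 3 past the threshold. Mock means were 16.3 and 19.2 for CD24, 13.9 and 11.2 for SDC1, 21.5 and 26.2 for PRTN3 and 13.7 and 13.5 for ADGRL3, so the sizes of these folds are uncertain too. With the pseudocount their log2 changes were 0.93, 0.61, 0.79 and 0.56, each called. The other named falls were NAV1, CDC42EP3, RNF175, DGKH, LINC01547 and VNN1, with log2 changes from -1.13 to -0.62, and the dim genes DZIP1, ANGPTL7 and BRINP3, with group means of 1.8 to 18.3. RNF175, LINC01547 and VNN1 also reached low levels, with RAD21 means of 24.8, 17.2 and 20.8 in experiment 2, and BRINP3 was not called with the pseudocount (-0.16, adjusted p = 0.0517). Leaving out 1 array ended the call of LINC01547 in 10 of 12 cases (adjusted p up to 0.0932), of BRINP3 in 8 (0.0692) and of DZIP1 in 7 (0.0700), and that of VNN1 without mock replicate 3 or RAD21 replicate 2 of experiment 2 (up to 0.0576). For all 12 rises and all 12 falls, every RAD21 array lay beyond every mock array of its experiment. That held for 236 of the 237 genes and for 696 of all 19752 (3.52%, where chance gives 0.5%). A call rests on the same difference in the same arrays and all but implies this separation, so for called genes it adds no support. Of 45 further probe sets for 16 of these 24 genes, 33 changed in the same direction, 7 of them past the threshold, and 0 passed it in the opposite direction. Of the 237 genes, 121 kept their call whichever array was left out, and 0 reversed. With the triplicates averaged, the 2 experiments were the replicates. An unadjusted p under 0.05 was then met by 1201 genes, not far above the share of 0.05 of all 19752 that chance gives. After adjustment limma called 0 genes. Without an experiment term it called 19, with a fold limit of 1.1 it called 59, and without mock replicate 3, RAD21 replicate 2 or RAD21 replicate 3 of experiment 2 it called 140, 141 and 151.

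Among the genes of granulocytic differentiation, 4 serine protease and related genes of the azurophil granule were called higher. PRTN3 rose 2.20-fold (1.14 ± 0.14, adjusted p = 0.00388), AZU1 1.67-fold (0.74 ± 0.09, adjusted p = 0.00422), ELANE 1.58-fold (0.66 ± 0.12, adjusted p = 0.0335) and CTSG 1.53-fold (0.61 ± 0.05, adjusted p = 0.000282), each with 6 of 6 RAD21 arrays above all mock arrays of the same experiment. ELANE, with mock means of 19.1 and 30.7, lost its call in 9 of 12 leave-outs (adjusted p up to 0.0891) and kept it only without mock replicate 1 or 3 of experiment 1 or mock replicate 1 of experiment 2. CTSG went from 226 ± 20 (SD, n = 3) to 325 ± 5 in experiment 1 and from 592 ± 19 to 958 ± 3 in experiment 2. MPO, the most abundant azurophil granule enzyme, averaged 7004 in mock and 7145 in RAD21 arrays and was not called. It was chosen after its values were seen. Its level is not far below the array maxima of 9612 to 10288, and whether so bright a signal still rises in proportion was not tested. Of the 25 measured members, 4 rose, 0 fell and 21 did not pass (6 higher and 1 lower adjusted over the list alone). The list as a whole was called higher by camera (mean log2 change 0.17, adjusted p = 0.0182), a call that was lost with an estimated correlation (adjusted p = 0.656) and with fry (adjusted p = 0.0522). It was also lost without mock replicate 1 (adjusted p = 0.143) and without RAD21 replicate 1 (adjusted p = 0.0660) of experiment 2.

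The cholesterol synthesis list rose. HMGCS1, which makes the precursor of mevalonate, rose 1.22-fold (0.29 ± 0.03, adjusted p = 0.00123), MSMO1 1.15-fold (0.20 ± 0.03, adjusted p = 0.0119) and SQLE, squalene epoxidase, 1.13-fold (0.18 ± 0.03, adjusted p = 0.0229), a call that was lost in 8 of 12 leave-outs (adjusted p up to 0.0646). Of the 16 measured members, 3 rose, 0 fell and 13 did not pass, with 5 higher adjusted over the list alone, and 15 had a positive value. The mean log2 change was 0.11 (camera adjusted p = 1.89e-09), 0.13 in experiment 1 and 0.09 in experiment 2. The call held with an estimated correlation (adjusted p = 0.0245) and with fry (adjusted p = 9.65e-05).

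Single members of other lists also passed, without the lists themselves doing so. Of the 25 monocytic differentiation genes measured, LYZ, lysozyme, rose 1.66-fold (0.73 ± 0.07), while IRF8, a transcription factor of monocyte and dendritic cell development, fell by 0.32 ± 0.05 on the log2 scale and MS4A7 fell by 0.33 ± 0.05 (list adjusted p = 0.988). PAX5, a B cell factor that leukaemias with the RUNX1-RUNX1T1 fusion often express, fell by 0.50 ± 0.06 and was the 1 called member of both the 17 B cell genes and the 20 genes associated with the fusion. The pro-apoptotic BIK rose 1.25-fold and the pro-apoptotic p53 target PMAIP1 fell by 0.19 ± 0.03. The imprinted gene DLK1 rose 1.47-fold, the histone gene H2BC12 1.36-fold and the endoplasmic reticulum gene SDF2L1 rose by 0.27 ± 0.05 on the log2 scale. JUN fell by 0.22 ± 0.04 and the co-chaperone gene DNAJB4 fell by 0.22 ± 0.04. JUN was near the threshold (adjusted p = 0.0438) and lost its call in 11 of 12 leave-outs (up to 0.104), and its 3 other probe sets, none of them called, had log2 changes of 0.00, -0.12 and -0.10. The other DNAJB4 probe set had -0.05, and DNAJB4 lost its call without mock replicate 3 of experiment 2 (0.0522). PMAIP1 and SDF2L1 lost theirs in 7 of 12 leave-outs each (up to 0.0638 and 0.0623), and IRF8 without RAD21 replicate 1 of experiment 1 (0.0508).

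The remaining lists gave no call over both experiments. None of the 34 S phase and DNA replication genes (mean log2 change 0.00), the 32 G2 and mitosis genes (-0.01), the 28 DNA repair and checkpoint genes (-0.01), the 34 interferon-stimulated genes (-0.06), the 24 TNF and NF-kB response genes (-0.04), the 26 stem and progenitor genes (0.06), the 23 clustered protocadherins (0.09), the 12 HLA class II genes (0.06) or the 9 HOXA and HOXB genes (-0.08) passed singly. The same held for the 25 hypoxia and glycolysis genes (-0.01), the 22 ribosome biogenesis and MYC targets (0.02) and the 23 ribosomal protein genes (0.00). Markers of other cells were in the same position, with mean log2 changes of -0.04 for the 17 erythroid genes, -0.02 for the 19 megakaryocyte and platelet genes, 0.04 for the 24 T and NK cell genes and -0.03 for the 22 genes of fibroblasts and adherent packaging cells. The 20 mast cell and basophil genes (-0.02) held CTSG as their 1 called member. The lists of 22 apoptosis regulators (0.00), 22 p53 targets (-0.02), 26 replication-dependent histones (0.04), 26 immediate early genes (-0.09), 18 imprinted genes (0.07), 14 heat shock genes (-0.01), 17 B cell genes (-0.04), 20 fusion-associated genes (-0.03), 23 cohesin genes (-0.07), 25 monocytic genes (-0.01) and 27 stress response genes (-0.21) did not pass either, the last with adjusted p = 0.135. The stress response list was called lower over both experiments without mock replicate 1 (adjusted p = 0.0350), mock replicate 2 (0.0388), mock replicate 3 (0.0430), RAD21 replicate 2 (0.0290) or RAD21 replicate 3 (0.0476) of experiment 2. These calls are at the preset correlation of 0.01, while the correlation estimated for this list was 0.372, which gave adjusted p = 0.987 over all arrays. Camera adjusted p-values of the other lists named here were 0.864 to 0.988. For 9 lists, none of them called, the mean, the median and the direction of the test did not share a sign.

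**Figure D2:**
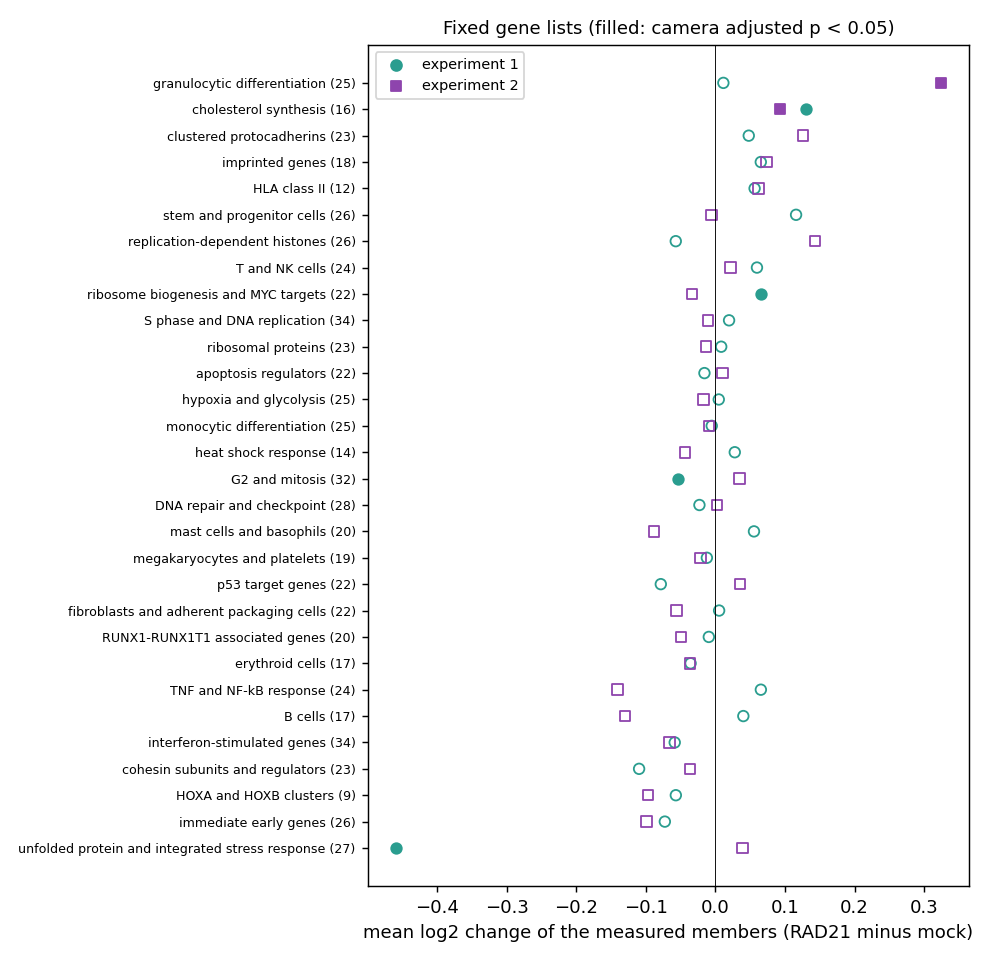
Mean log2 change (RAD21 minus mock) of the measured members of each of the 30 lists in experiment 1 (circles) and experiment 2 (squares), with the number of members in parentheses and filled symbols for camera adjusted p under 0.05 with the preset correlation. The stress response list lies at -0.46 in experiment 1 and 0.04 in experiment 2, and the cholesterol list is called in both, in experiment 2 only with the preset correlation (adjusted p = 0.181 with an estimated one).

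In experiment 1 alone, the gene list with the smallest p was the unfolded protein and integrated stress response, which fell. Some of its members are targets of ATF4, the transcription factor of the amino acid response, which was itself not called there (-0.18, adjusted p = 0.0910). The cystine transporter gene SLC7A11 fell by 2.54 ± 0.12 on the log2 scale, the glutathione-degrading CHAC1 fell by 2.13 ± 0.36, the asparagine synthetase gene ASNS fell by 0.94 ± 0.05, SESN2 fell by 0.95 ± 0.06 and the serine synthesis gene PSAT1 fell by 0.77 ± 0.04. These 5 genes were chosen after their values were seen. CHAC1, at 62.1 in mock and 14.2 in RAD21 arrays, lost its call in 9 of 12 leave-outs (adjusted p up to 0.0961). Of the 27 measured genes of the list, 13 fell and 0 rose in experiment 1 (16 lower and 2 higher adjusted over the list alone). The mean log2 change was -0.46 (camera adjusted p = 2.24e-14, adjusted p = 0.00212 with an estimated correlation). Over all genes, 269 were called in experiment 1, 112 higher and 157 lower (73 and 105 with median centring). Cholesterol synthesis (0.13) and ribosome biogenesis and MYC targets (0.07) were called higher and G2 and mitosis (-0.05) lower. With an estimated correlation their adjusted p-values were 0.0398, 0.141 and 0.460. The G2 and mitosis call was also lost without mock replicate 2 (0.0680) or RAD21 replicate 3 (0.134) of experiment 1. Fitted to its own 6 arrays alone, experiment 1 gave 35 calls, and leaving out 1 of its arrays gave 125 without mock replicate 1, 135 without mock replicate 2, 152 without mock replicate 3, 167 without RAD21 replicate 1, 187 without RAD21 replicate 2 and 163 without RAD21 replicate 3.

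In experiment 2 alone, 453 genes were called, 274 higher and 179 lower (200 and 87 with median centring). RUNX2 rose 3.43-fold, CUX2 4.02-fold, ABLIM1 5.50-fold from a mock mean of 14.9, PRTN3 2.76-fold, AZU1 1.96-fold and CTSG 1.62-fold. The granulocytic differentiation list was called higher (mean log2 change 0.32, 3 members higher and 22 not called; camera adjusted p = 0.000579, adjusted p = 0.0538 with an estimated correlation), and so was cholesterol synthesis (0.09, adjusted p = 0.000570, and adjusted p = 0.181 with an estimated correlation). The stress response list was not called there (0.04, adjusted p = 0.101). Fitted to its own 6 arrays alone, experiment 2 gave 123 calls. Leaving out any 1 of its arrays in the fit of the 4 group means lowered the 453 calls to between 223 and 290. The fewest came without RAD21 replicate 2.

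**Figure D3:**
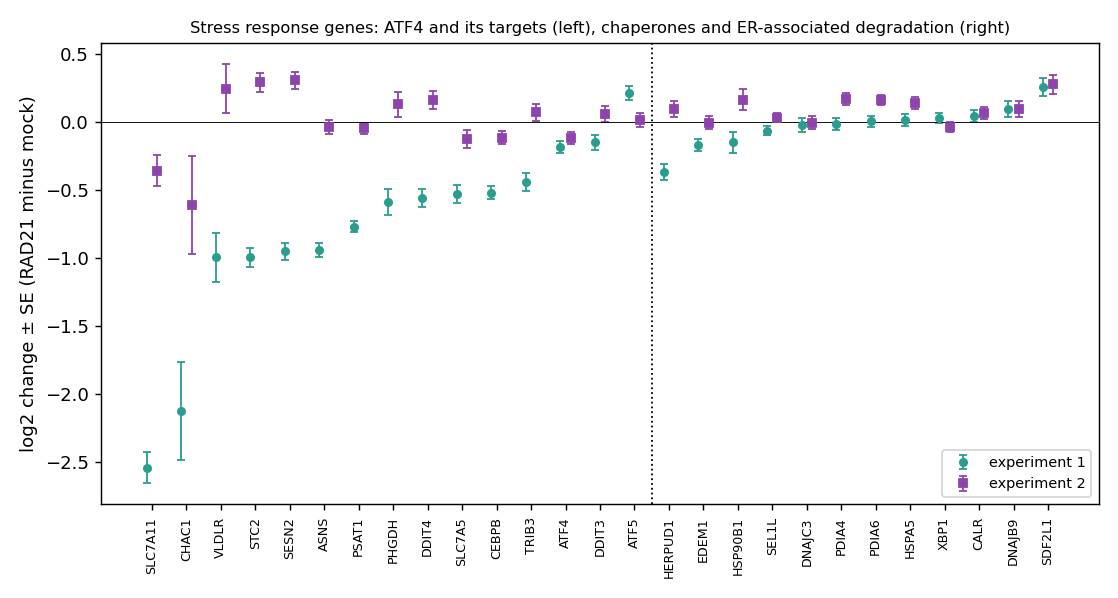
Log2 change ± SE (RAD21 minus mock) of the 27 measured genes of the stress response list in experiment 1 (circles) and experiment 2 (squares), with ATF4 and its targets left of the dotted line and chaperones and degradation genes right of it. SLC7A11 lies at -2.54 in experiment 1 and -0.36 in experiment 2, and ASNS at -0.94 and -0.04.

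The change differed between the experiments for 190 genes, 121 with the higher change in experiment 2 and 69 with the higher change in experiment 1 (61 and 32 with median centring). The signs were opposite for 144 of them. Leaving out any 1 of the 12 arrays gave 76 to 119 such genes, the fewest without mock replicate 1 of experiment 2. The amino acid transporter SLC38A1 went from -0.55 in experiment 1 to 1.51 in experiment 2 and the vesicular monoamine transporter SLC18A2 from 1.52 to -0.73, both chosen after their values were seen. Among the named rises, ABLIM1 (difference 1.30, adjusted p = 0.0106), CUX2 (0.87, adjusted p = 0.0106) and RUNX2 (0.55, adjusted p = 0.0339) were higher in RAD21 arrays of both experiments, and by more in experiment 2. NAV1 fell in both, and by more in experiment 2 (-0.76, adjusted p = 0.0183). The difference in RUNX2 lost its call in 11 of 12 leave-outs (up to 0.0949), and that in NAV1 without mock replicate 2 of experiment 1 or RAD21 replicate 2 or 3 of experiment 2 (up to 0.0550). SLC38A1 was not called in experiment 1 without its mock replicate 1 (0.0632). The stress response list differed by 0.50 (10 members with a higher change in experiment 2; camera adjusted p = 5.39e-17, adjusted p = 0.00116 with an estimated correlation). Another 6 lists differed with the preset correlation, with adjusted p-values of 0.0941 to 0.384 with an estimated correlation. Of the 190 genes, 59 kept their call whichever array was left out.

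The experiments shared part of their changes. Of the 269 genes called in experiment 1, 177 (65.8%, Wilson 95% interval 59.9 to 71.2) changed in the same direction in experiment 2, and 71 were also called there in that direction. Of the 453 called in experiment 2, 305 (67.3%, 62.9 to 71.5) had the same direction in experiment 1. Both intervals count genes as independent, which they are not, and are too narrow. Calls shared in direction were 43 higher genes and 28 lower genes, where independent lists of these sizes would share 1.55 and 1.42. The experiments had no array in common, but both lists of calls used the same estimate of each gene's spread, made from all arrays. Genes with a small spread are more easily called in both, so the lists are not independent and 1.55 and 1.42 are likely too low. Sharing the spread favours neither direction. Of the 82 called in both experiments, 71 had the same direction and 11 had opposite directions. Across genes, which are not independent replicates, the log2 changes of the experiments correlated at Pearson's r = 0.0554 (Spearman's rho = 0.0404) over all 19752 genes and at r = 0.293 (rho = 0.362) over the 640 called in either. All 237 genes called over both experiments had the same direction in each, which a test of the average change favours by its construction, and 14 of them differed in size between the experiments.

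**Figure D4:**
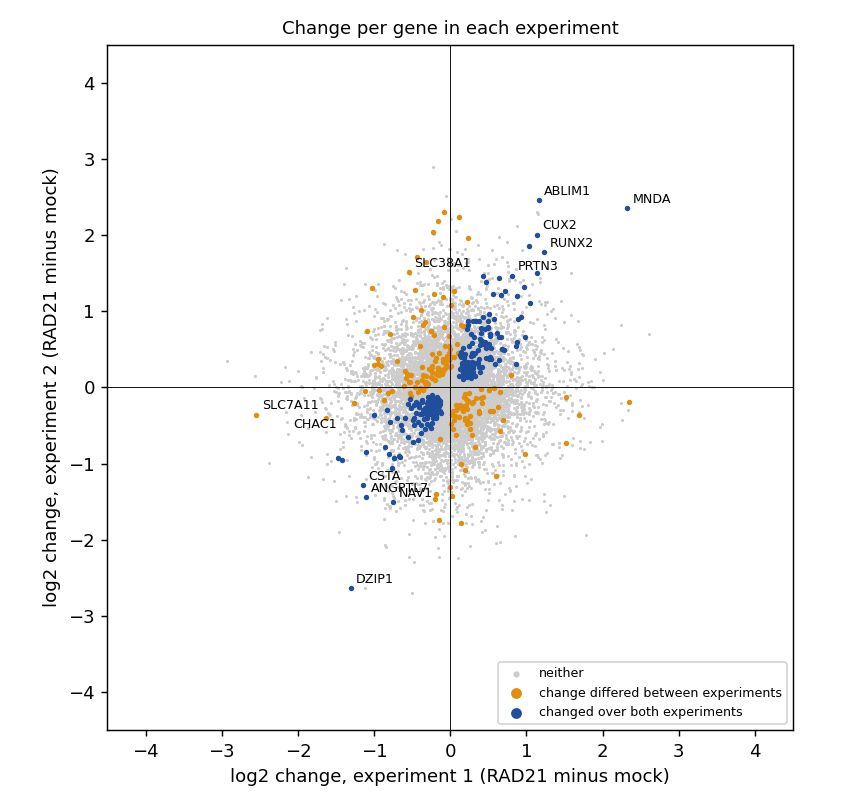
Log2 change (RAD21 minus mock) of each of the 19752 genes in experiment 1 (horizontal) and experiment 2 (vertical), with the 237 genes called over both experiments in blue, other genes whose change differed between the experiments in orange and all others in grey. MNDA lies at 2.32 and 2.35, SLC7A11 at -2.54 and -0.36, and SLC38A1 at -0.55 and 1.51.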

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

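The tests of swapped arms, of probe sets outside the transferred copy and of admixed granulocytes were chosen only after the result was seen, and so was the division of the stress response list into 2 parts.

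The splits exchange arrays between the arms of an experiment. They set a count against the spread between arrays, which may be technical, and leave chance differences between cultures open. With triplicates averaged limma called 0 genes, and the 1201 at an unadjusted p under 0.05 were not far above the share that chance gives. Of 100 drawn splits of the arrays within each experiment (200 possible), 1, the real one, gave as many changed genes over both experiments, 237 against a highest other of 16, so chance in which arrays carry which label can be excluded, and the same holds for changes of at least 1.2-fold (1 of 100, 166 against 12). For genes whose change differed between the experiments, 2 of 100 gave as many as the real 190, so chance of that kind can be excluded. The highest other, 483, came from the split that exchanges the arms of 1 experiment, which by construction turns a shared change into a difference and so points to the shared structure of the arms. Among splits that keep the arms of neither experiment, the highest count was 4. For the number of gene lists called, 20 of 100 splits gave at least the real 2, with a highest other of 6, and chance cannot be excluded. For the cholesterol list by itself the real split had the smallest camera p of the 100, 6.32e-11 against 2.43e-07 for the next. For the granulocytic differentiation list the real split was also the smallest, but by little, 0.00122 against 0.00158. In both cases the next split kept the arms of 1 experiment. Both lists were looked at singly because they passed in these data. In each experiment alone the 10 splits are too few for a share under 0.05, with 1 of 10 as high in both: 269 against a highest other of 3 in experiment 1, and 453 against 6 in experiment 2.

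RAD21's own probe sets were not called higher in RAD21 arrays, and in experiment 1 the brighter one had the lower mean there. Arms swapped in 1 experiment would turn its changes against those of the other. Of the 453 genes called in experiment 2, 67.33% had the same direction in experiment 1. The exact binomial 95% interval, 62.8 to 71.63, counts genes as independent, which they are not, so it is too narrow. The share goes against a swap in 1 experiment without excluding it, and leaves a swap in both untested. Probe sets that do not read the transferred copy could also leave RAD21 flat. The higher of both changes in experiment 1 was 0.0798 on the log2 scale, but with the place of the probe sets not given in the sources used here, such probe sets and a weak rise cannot be told apart. No biological explanation was tested.

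The unfolded protein and integrated stress response list differed most between the experiments (0.50 on the log2 scale, adjusted p = 5.39e-17, and adjusted p = 0.00116 with an estimated correlation), and its 15 members that are ATF4 or its targets, a part not tested by itself, held most of the calls, with 12 of the 13 called lower in experiment 1 and a median change of -0.59 there against 0.02 in experiment 2. A single array of experiment 1 as the source is argued against by the leave-outs, whose highest adjusted p was 6.968e-15 (0.000748 to 0.00465 with an estimated correlation). A raised amino acid response in the mock cells of experiment 1 is a candidate explanation: relative to all genes, these 15 members had a median 0.5563 higher in mock cells of experiment 1 than of experiment 2 (quartiles 0.08 to 0.73, 12 of 15 above 0), against -0.16 between the RAD21 arms, while the 12 chaperone and degradation genes had -0.26 and -0.30. The gaps between experiments and the pattern share the same arrays, so only the sign of the mock gap was free to come out otherwise. An effect of RAD21 in experiment 1 alone, or a difference in culture, stays open.

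The azurophil granule genes CTSG, PRTN3, AZU1 and ELANE were higher in RAD21 arrays, and the granulocytic differentiation list changed more in experiment 2 (difference 0.31, adjusted p = 0.0241, 0.0941 with an estimated correlation, and 0.0611, 0.0540 and 0.0735 without RAD21 replicate 1 or 3 of experiment 1 or RAD21 replicate 1 of experiment 2). Under both quantile normalization and median centring 4 of 4 kept their call and direction, though ELANE lost its call in 9 of 12 leave-outs (adjusted p up to 0.0891). Array medians lay close together, at 22.33 to 23.01 in experiment 1 and 20.45 to 21.83 in experiment 2. Centring could thus shift values only slightly, so keeping the calls was nearly fixed in advance. Medians this close argue against median scaling as the source of rises of 0.61 to 1.14 on the log2 scale. Admixed mature granulocytes would raise their own markers, each on its own probe set. In experiment 1, 9 such markers had a median log2 change of -0.2823 (quartiles -0.40 to -0.18, highest 0.02) against 0.50 for AZU1, the smallest rise of the 4. Most of the 9 had mock means of only 2.64 (LTF) to 21.7 (CAMP) over both experiments, with CXCR2 (56.9) and MMP9 (124) brighter. Changes at such low levels are imprecise, so the values argue only weakly against such cells in experiment 1. In experiment 2 such cells and a change in the cells themselves cannot be told apart, since the median was 0.0278 but the upper quartile, 0.72, reached the 0.67 of ELANE, with most markers dim and 0 of 9 called higher. An effect of RAD21 on these genes stays open as untested, in a cell line sorted on GFP, a sort that would remove unmarked cells of other types.

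The other differences between the experiments (change in experiment 2 minus change in experiment 1, log2, tested in the fit of all 12 arrays) are given as values. Among named genes they were ABLIM1 1.30 (adjusted p = 0.0106), CUX2 0.87 (0.0106), RUNX2 0.55 (0.0339), NAV1 -0.76 (0.0183), DUSP4 -0.63 (0.0137), TP53INP1 0.56 (0.0126), CEBPB 0.40 (0.0364) and ESCO1 0.31 (0.0443). Leaving out 1 array ended the call for ESCO1 in 12 of 12 cases (up to 0.116), for RUNX2 and CEBPB in 11 (up to 0.0949 and 0.0973) and for NAV1 without mock replicate 2 of experiment 1 or RAD21 replicate 2 or 3 of experiment 2 (up to 0.0550). Among gene lists they were, with adjusted p at the preset correlation and then at an estimated one, cohesin 0.07 (0.0419 and 0.187), G2 and mitosis 0.09 (0.00253 and 0.290), heat shock -0.07 (0.0376 and 0.384), ribosome biogenesis and MYC targets -0.10 (0.000443 and 0.0941) and TNF and NF-kB response -0.21 (0.0173 and 0.0941). At the preset correlation the call was lost for cohesin in 10 of 12 leave-outs (up to 0.122), for heat shock in 7 (up to 0.130) and for TNF and NF-kB without RAD21 replicate 3 of experiment 1 (0.0558). Outside the genes compared in the report, 10 of 13522 probe sets without a single gene name were called when all probe sets were tested, 2 higher and 8 lower in RAD21 arrays. Groups of 3 arrays were not tested for single arrays far from the others.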

How the results depend on the processing

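Tests with a pseudocount of 16, with the other RAD21 probe set and of the shared direction under each alternative were chosen only after the result was seen.

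No called result reversed its direction under any alternative. RAD21 was called under none of them, with changes of -0.03 to 0.01 on the log2 scale from the same probe set and 0.28 (adjusted p = 0.417) from the other. With quantile normalization every count stayed within 1.5 times its value, and 231 of the 237 genes kept their call and direction. With a random block of arm within experiment 237 of them did, and with the pseudocount 236. The median change of all genes lay between -0.01 and 0.01 unscaled and under both scalings.

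Centring each array on its median gave 178 genes in experiment 1, 287 in experiment 2 and 93 that differed, and the cause was not tested. The share of higher genes went from 55.3% to 62.7% over both experiments and from 60.5% to 69.7% in experiment 2. Of the 237 genes, 159 kept their call there. Without the dimmest 40% of genes 536 changed over both experiments, 572 in experiment 1 and 742 in experiment 2, and 437 differed. Fewer genes were tested there and the spread was estimated without the noisiest ones, and 223 of the 237 kept their call. A variance prior with trend and robust gave 574, 714, 867 and 538, with 227 kept. Testing all probe sets called 177 genes over both experiments, with 111 of the 237 kept, and 102 that differed.

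Replicate number as a block gave 19 genes over both experiments, 19 of at least 1.2-fold, 13 in experiment 1, 89 in experiment 2, 6 that differed and 1 list. Residuals of arrays with the same number correlated at -0.02 to 0.07 over all genes, and those with different numbers at -0.05 to 0.04. In the brightest 60% of genes the ranges were -0.12 to 0.14 and -0.15 to 0.11. The ranges overlap, so the values show no clear pairing by replicate number without excluding it. If the numbers pair nothing, this block only spends degrees of freedom. Without an experiment term 19 genes were called, 19 of them at least 1.2-fold, since the difference between experiments then counts as noise. With triplicates averaged limma called 0 genes, 0 of at least 1.2-fold and 1 list, with 1 residual degree of freedom. There 1201 genes had an unadjusted p under 0.05, not far above the share of 0.05 of all 19752 that chance gives. Fitted to its own arrays, experiment 1 gave 35 genes and experiment 2 gave 123, with fewer arrays to estimate the spread. A fold limit of 1.1 gave 59. Camera with an estimated correlation called 1 list and fry 1, cholesterol synthesis in each case.

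Leaving out each array in turn gave RAD21 changes of -0.03 to 0.01, 140 to 209 genes over both experiments, 112 to 157 of at least 1.2-fold, 1 to 3 lists, 125 to 203 genes in experiment 1, 223 to 433 in experiment 2 and 76 to 119 that differed. Of the genes called in experiment 1, the share with the same direction in experiment 2 was 65.6% to 72.0% over these leave-outs, 76.9% with the replicate block and 77.1% with each experiment fitted alone, where fewer genes were called. The cholesterol synthesis list kept its call in all 24 alternatives (adjusted p 1.52e-13 to 0.0245). The granulocytic differentiation list lost its call in 6: with the replicate block (0.109), without mock replicate 1 (0.143) or RAD21 replicate 1 (0.0660) of experiment 2, with averaged triplicates (0.951), with an estimated correlation (0.656) and with fry (0.0522). Of 41 named genes called, 41 were reversed by no alternative and 10 kept their call in every alternative but averaging and the replicate block. JUN lost its call in 16 of 22 alternatives and ELANE in 13. The stress response list gained a call in 5 leave-outs at the preset correlation (0.0290 to 0.0476, against 0.987 over all arrays with an estimated one). Signal over background limits precision: the median SD of log2 values within a group was 0.66 in the dimmest class of genes and 0.048 in the brightest.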

Other observations

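The genes in this part, and the tests of them, were chosen only after the result was seen.

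The genes in this paragraph are single calls among the 237 over both experiments, and no list of them was tested. RUNX3, a second relative of RUNX1, rose 1.53-fold (0.61 ± 0.09, log2, adjusted p = 0.0119), and CBFA2T3, a corepressor of the same family as the fusion partner RUNX1T1, rose 1.51-fold (0.59 ± 0.05, adjusted p = 0.000318). SERPINA1, the antitrypsin that inhibits neutrophil elastase, rose 1.86-fold (0.89 ± 0.05, adjusted p = 4.94e-05), and the elastase inhibitor SLPI rose by 0.68 ± 0.07 (adjusted p = 0.00175). The granule proteoglycan SRGN rose 1.46-fold (0.55 ± 0.03, adjusted p = 3.89e-05) and the class I gene HLA-C 1.38-fold (0.46 ± 0.05, adjusted p = 0.00243), read by a probe set that can match several class I transcripts. For each of these 6 genes, 6 of 6 RAD21 arrays lay above every mock array of their experiment, a separation that the call of a gene all but implies.

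The C-type lectin genes CLEC2B (-0.30 ± 0.05, adjusted p = 0.0203), CLEC4D (-0.27 ± 0.05, adjusted p = 0.0425), CLEC4E (-0.26 ± 0.04, adjusted p = 0.0175) and CLEC5A (-0.20 ± 0.03, adjusted p = 0.00787) fell, each with 6 of 6 RAD21 arrays below every mock array of their experiment. The prostaglandin receptor PTGER4 (-0.39 ± 0.04, adjusted p = 0.000897) and the ATP-gated channel P2RX7 (-0.31 ± 0.06, adjusted p = 0.0249) also fell. Leaving out 1 array ended the call of CLEC4D in 9 of 12 cases (up to 0.104), of CLEC2B and P2RX7 in 5 each (up to 0.0604 and 0.0694) and of CLEC4E without mock replicate 3 or RAD21 replicate 2 of experiment 2 (up to 0.0537). These are single genes picked from those called. No list of surface receptors was tested, and other receptor genes rose, among them CXCR4 (0.99), CD244 (0.42) and S1PR3 (0.34).

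Single genes of amino acid metabolism outside the list were picked because they fell in experiment 1 and differed between the experiments, so they say nothing about such genes as a group. They were ALDH1L2 (-1.12 in experiment 1 and -0.04 in experiment 2, adjusted p of the difference 0.00188), CARS1 (-0.61 and 0.02, 0.00909), PCK2 (-0.39 and -0.01, 0.00899), PSPH (-0.52 and -0.15, 0.0395) and CBS (-0.53 and 0.07, 0.0464). The difference lost its call in 10 of 12 leave-outs for PSPH and for CBS (up to 0.102 and 0.114), and CBS was not called in experiment 1 in 4 (up to 0.0649). RNASE2, a ribonuclease of eosinophil and neutrophil granules, changed by 0.22 in experiment 1 and 1.12 in experiment 2 (adjusted p of the difference 0.000632).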
